A study of Bos taurus with 9 samples.

How the data were processed

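RNA of bovine oocytes at metaphase II was sequenced in 9 libraries, 3 from control oocytes, 3 from oocytes exposed to microplastics and 3 from oocytes given microplastics and taurine. Per the labels, total RNA was extracted with TRIzol and libraries were prepared with the sequencing provider's standard protocol. The aligner, the counting program, their versions, the genome build and the annotation are not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

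The deposited table has 22590 rows, each a transcript with its gene ID. Per the file headers the authors deposited estimated counts, which were assigned to transcripts by a program not given in the sources used here, are not whole in every row and were not normalized. Per the file headers it also holds FPKM and TPM values made by the authors, and the deposited TPM columns sum to 1000000 or 1000001 in each library. A further set of deposited columns, treated here as a signal, equals the rounded counts multiplied by 1 factor per library, and the authors' group means stand beside them. The tests used the estimated counts. FPKM entered only through the transcript length that the ratio of counts to FPKM implies, and TPM, the authors' scaled signal and their means were not used here.

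Estimated counts were summed over the transcripts of a gene, giving 17852 genes, and rounded to whole numbers. Symbols came from a RefSeq gene table matched on gene ID, which named 16995 genes (95.2%). Libraries held 21.17 to 22.74 M estimated reads. A floor of 3 counts in a library corresponds to 0.132 to 0.142 CPM, and it covers counting error only, since reads were not marked with molecular identifiers.

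Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the package's expression filter (minimum count 10, minimum total 15), a robust fit with 1 coefficient for each group over all 9 libraries, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and 13206 genes were tested. Means are TMM-scaled CPM with SD over 3 libraries, and errors of log2 fold changes are SE. Gene lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and a prior count of 2 in log2 CPM, adjusted over the 29 lists with at least 5 measured members. Camera compares a list with the other genes, and fry asks whether its members move one way on balance. The comparisons, tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined.

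Genes were named by this rule. In each comparison it takes the 10 rising and 10 falling genes with the largest fold change among those with a symbol, an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the groups' libraries. Where none passed in a direction, it takes the 3 genes of that direction with the smallest unadjusted p, with no condition on symbol or level. That step was first run with such conditions by mistake and was brought back to the fixed wording after its genes had been seen. It adds up to 2 rising and 2 falling members of each described list, genes fixed by name whatever their values (SOD1, SOD2, CAT, GPX1, GPX4, BAX, BCL2, SLC6A6, GDF9 and BMP15), and the 10 genes with the smallest adjusted p in both of the first comparisons with opposite signs. BCL2 and SLC6A6 had 0 to 4 reads in every library and were not tested. A further gene fixed by name is not reported here.

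For the return with taurine, genes were called with 1 microplastics library left out, and the sign of the return was read from that library against the taurine libraries, averaged over the 3 choices. The same share was computed in 10 simulated data sets in which the taurine libraries were drawn like microplastics libraries.

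Alternatives fixed beforehand were DESeq2 size factors, no filter, a filter of 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the compared groups, the replicate number as a block, an absolute log2 fold change of at least 1, an adjusted p under 0.1, each library left out in turn, and, for lists, an estimated correlation and fry. Chosen after seeing the data were scaling by library size only, testing transcripts one by one, leaving out control 3 and taurine 3 together, and removing a smooth trend on transcript length in each library. A changed sign counts as reversed here, for named genes that were never called as well. For lists, a changed sign of the median counts too. These labels were set after the values had been seen.

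The tests were also run on simulated counts for microplastics minus control, drawn for the 13206 genes from their means over all libraries and their spread within groups. Of 50 genes changed at each size, 5 were called at 1.5-fold, 13 at 2-fold, 42 at 4-fold and 47 at 8-fold, with 5 false calls. Only these genes were changed, far fewer than the real comparison called, so the adjusted threshold was stricter than in the data. A simulated list of 40 genes shifted 1.5-fold had a camera adjusted p of 4.5e-20, and 0 of 29 unshifted lists were called. Genes were drawn independently of each other there. The test therefore says nothing about false calls of lists whose members move together, such as the cytosolic ribosomal proteins (estimated correlation 0.389). No 2 libraries of a group differed by as little as sampling noise. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.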

Results

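Transcriptomes were measured in bovine oocytes that had reached metaphase II, the stage at which a mammalian egg is ready for fertilization. Control oocytes, oocytes exposed to microplastics, and oocytes given microplastics together with taurine, an amino sulfonic acid, were represented by 3 libraries each. Libraries held 21.17 to 22.74 M estimated reads, and the mean number of genes with at least 1 read was 15444 in control, 15844 with microplastics and 15522 with microplastics and taurine. BTG4, an oocyte gene of maternal mRNA decay, took 5.22% ± 0.43 of reads in control, 2.45% ± 0.40 with microplastics and 4.81% ± 0.46 with taurine (SD, n = 3). TMM factors were 0.835 to 0.972 in control, 1.214 to 1.253 with microplastics and 0.841 to 0.958 with taurine.

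The first principal component, with 46.2% of the variance, separated the 3 microplastics libraries from the others. Control 3 and taurine 3 each stood with the other group. Over all tested genes, control 3 correlated at 0.976 with taurine 1 and taurine 2 and at 0.962 and 0.964 with control 1 and control 2, while taurine 3 correlated best with control 2, at 0.977.

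**Figure D1:**
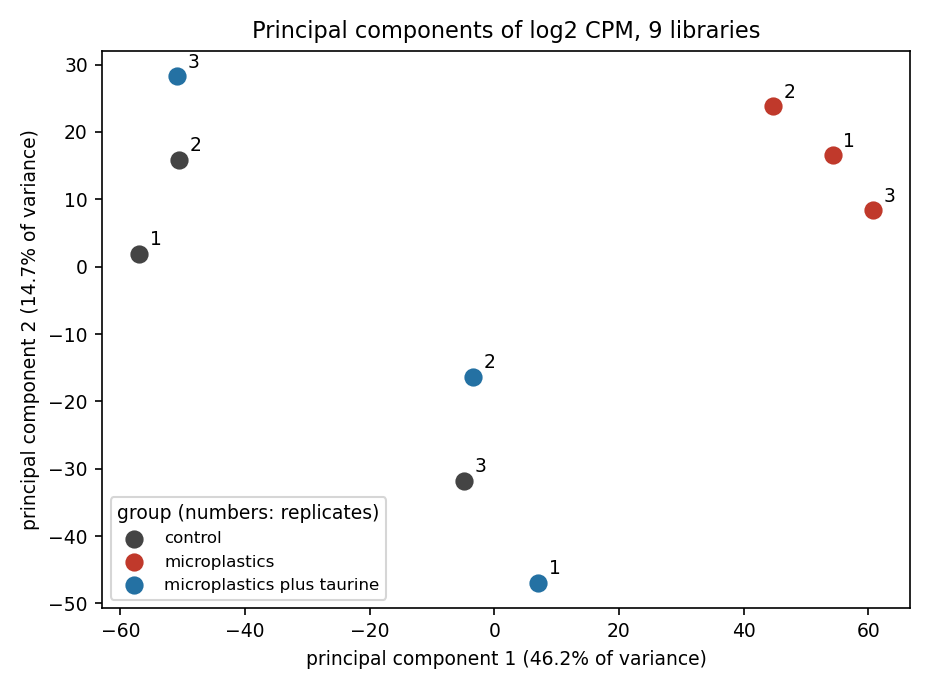
Position of the 9 libraries on the first and second principal components of log2 CPM, with 46.2% and 14.7% of the variance, 1 point per library, coloured by group and numbered by replicate. The microplastics libraries lie apart on the first component, control 3 lies near taurine 1 and 2, and taurine 3 near control 1 and 2.

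The first comparison asked what exposure to microplastics changed. Transcripts of THOC6, a subunit of the THO complex of mRNA export, fell from 132.7 ± 24.5 CPM in control to 5.90 ± 1.34 (SD, n = 3), a log2 fold change of -4.49 (adjusted p = 7.99e-06). NUDCD2 fell from 143.8 ± 33.7 to 8.35 ± 2.16 CPM and SMIM11 from 138.5 ± 14.4 to 10.1 ± 4.70 CPM. DHX58, a cytosolic sensor of viral RNA, rose from 14.02 ± 0.719 to 54.6 ± 3.92 CPM (log2 1.96, adjusted p = 2.96e-05), and VPS16, a subunit of the tethering complexes of the endolysosomal system, rose from 10.8 ± 3.10 to 43.1 ± 6.36 CPM. In all, 3213 of 13206 genes were called, 1278 higher and 1935 lower.

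Among the other large rises, NEFH, the heavy neurofilament subunit, rose from 4.56 ± 2.75 to 24.2 ± 1.98 CPM, MICAL1 from 4.59 ± 2.52 to 21.04 ± 3.22 and WASHC1 from 5.95 ± 2.23 to 25.9 ± 3.66. DDX51, KREMEN1, ZNF777 and RAB24 rose by log2 2.39, 2.02, 2.02 and 1.98. Among falls, PLAC1 went from 14.8 ± 4.46 to 0.795 ± 0.292 CPM, FAM200B from 15.5 ± 4.66 to 1.22 ± 0.585 and VEGFD, a vascular growth factor, from 8.22 ± 0.630 to 0.639 ± 0.462. RND3, GABRA4 and LAMP3 fell as well, RND3 to 0.160 ± 0.108 CPM, which is near the floor of 3 counts. COL6A5 rose by log2 2.21, and its call was lost without control 2 (1.79), microplastics 1 (2.03) or microplastics 3 (2.05). TIMP1, an inhibitor of matrix metalloproteinases, fell by 3.87 on the log2 scale, and that call was lost without control 1 (-4.14), control 2 (-2.90), control 3 (-4.21), microplastics 1 (-3.57) or microplastics 3 (-3.56).

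Genes for cytosolic ribosomal proteins were lower with microplastics. Of 77 measured members 50 fell, 1 rose and 26 did not pass (57 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.87 that was -0.38 with scaling by library size only (33 falls and 7 rises). RPS19 fell from 81.6 ± 7.83 to 7.56 ± 2.73 CPM and RPL23 from 47.9 ± 11.2 to 7.84 ± 2.27 CPM, while RPL4 rose by log2 0.54, a call lost without any of the control or microplastics libraries (0.46 to 0.63). Camera gave an adjusted p of 2.24e-15, and the adjusted p = 0.785 with an estimated correlation. These genes have near-identical copies and pseudogenes, so their counts are uncertain.

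Nuclear genes of the respiratory chain were lower too. Of 38 complex I genes 22 fell, 1 rose and 15 did not pass (24 and 1 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 0.000188), among them NDUFA6 (184.7 ± 30.8 to 43.9 ± 4.74 CPM) and NDUFB1 (219.0 ± 52.5 to 62.2 ± 7.63 CPM). The complex I median was -0.59 without control 1, and with scaling by library size only it was -0.53 with 11 falls and 7 rises. Of 25 genes of complexes II to IV 11 fell and 1 rose (13 and 2 adjusted over the list alone; median -0.87; camera adjusted p = 0.00413), against 6 falls, 4 rises and a median of -0.34 with scaling by library size only, and -0.49 without control 1. The 2 succinate dehydrogenase subunits named here moved apart, SDHD falling from 70.4 ± 6.40 to 17.6 ± 1.43 CPM and SDHA rising from 10.8 ± 2.06 to 31.6 ± 3.97 CPM. ATP synthase genes counted 9 falls and 1 rise of 18 (10 and 1 adjusted over the list alone; median -0.59; camera adjusted p = 0.032), with ATP5MF falling from 51.5 ± 14.3 to 18.4 ± 6.25 CPM and ATP5F1B, the catalytic beta subunit, rising from 48.2 ± 12.7 to 109.3 ± 11.3 CPM. With scaling by library size only the ATP synthase counts turned round to 1 fall and 4 rises, with a median of -0.09 and no call by camera. That call was also lost without control 1 (-0.51), control 2 (-0.63) or microplastics 3 (-0.57), with a filter of 5 CPM in 3 libraries (-0.54) and with fry (adjusted p = 0.0992). Mitochondrial ribosomal protein genes counted 21 falls and 4 rises of 77 (24 and 4 adjusted over the list alone; camera adjusted p = 0.0194), and their median of -0.29 turned to 0.21 with scaling by library size only (15 rises and 13 falls). The call of that list was lost without control 1 (-0.07) and with a filter of 5 CPM in 3 libraries (-0.24). The adjusted p = 0.785 with an estimated correlation for each of these 4 lists.

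Fold change followed transcript length. Over the 12230 tested genes with a length (92.6%), the median log2 change went from -0.36 in the shortest of 5 length classes, of median length 736 nt, to 0.28 in the longest, of 4815 nt. Genes that fell numbered 638 in the shortest class and 173 in the longest, and genes that rose 85 and 429. With the length trend removed in each library, 1 of the 7 called lists kept its call, the cytosolic ribosomal proteins, with a median of -0.49 (camera adjusted p = 0.000613 at the preset correlation). With an estimated correlation that list was not called even before removal (adjusted p = 0.785). The medians became -0.39 for complex I, -0.29 for complexes II to IV, -0.11 for ATP synthase, 0.00 for mitochondrial ribosomal proteins, -0.58 for the oocyte gene list (adjusted p = 0.163) and 0.22 for DNA and histone modification (adjusted p = 0.304), and ATP5MF lost its call (-0.65).

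**Figure D2:**
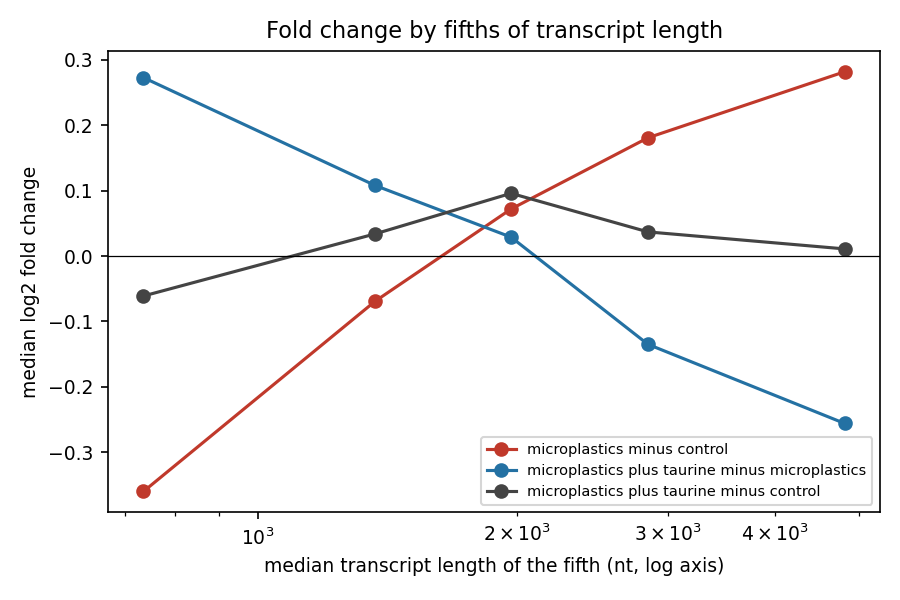
Median log2 fold change in each of 5 classes of transcript length against the median length of the class in nt on a log axis, 1 line per comparison. From the shortest to the longest class, microplastics minus control runs from -0.36 to 0.28 and microplastics plus taurine minus microplastics from 0.27 to -0.26.

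A list of oocyte genes, many of them secreted or of the zona pellucida but with H1-8 and PABPC1L among its members, counted 7 falls and 1 rise of 15, also adjusted over the list alone. Its median was -0.86 (-0.40 with 5 falls and 2 rises with scaling by library size only, -0.51 without control 1). OOSP2 fell from 11380 ± 1321 to 5138 ± 942.5 CPM and H1-8, the oocyte linker histone, from 5491 ± 782.9 to 2717 ± 480.2 CPM, while PABPC1L rose from 5.92 ± 1.60 to 15.2 ± 1.87 CPM. Camera gave an adjusted p of 0.032, and the adjusted p = 0.785 with an estimated correlation. The call of the list was lost without control 3 (-0.67) and with a filter of 5 CPM in 3 libraries (-0.82). GDF9 was at 1401 ± 1054 CPM in control and 559.5 ± 26.4 with microplastics (adjusted p = 0.0277). Control 1 alone held 2620 CPM, and the call was lost without control 1 (-0.51), microplastics 1 (-1.27), microplastics 2 (-1.34) or microplastics 3 (-1.31).

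Genes for modification of DNA and histones counted 9 rises and 2 falls of 39 (12 and 3 adjusted over the list alone; median 0.34, and 0.81 with 22 rises and 1 fall with scaling by library size only), with the histone methyltransferases SETDB1 (48.6 ± 3.85 to 87.9 ± 14.8 CPM) and EHMT2 (55.3 ± 9.55 to 102.9 ± 9.55 CPM) rising and UHRF1 falling from 3427 ± 474.8 to 1643 ± 269.7 CPM. Camera gave an adjusted p of 0.0194, and the adjusted p = 0.785 with an estimated correlation. Maternal-effect genes counted 8 rises and 3 falls of 28 (9 and 3 adjusted over the list alone, and 15 and 1 with scaling by library size only), with NLRP13 and ZAR1 rising by log2 1.28 and 1.00 and DPPA3 falling from 11050 ± 527.6 to 6280 ± 262.8 CPM, and camera did not pass (adjusted p = 0.132).

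Of the antioxidant enzymes and NRF2 targets, 10 fell, 2 rose and 34 did not pass of 46 (13 and 2 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.563, and 0.0452 by fry). It turned to 0.34 with scaling by library size only (15 rises and 7 falls) and to 0.07 with the length trend removed (camera adjusted p = 0.988). CAT, which encodes catalase, fell from 342.3 ± 44.7 to 129.0 ± 14.8 CPM (log2 -1.41, adjusted p = 0.000709), and PRDX3, a mitochondrial peroxiredoxin, from 430.1 ± 59.6 to 115.3 ± 3.63 CPM. SOD1 (-0.31), SOD2 (0.51), GPX1 (-0.65) and GPX4 (0.29) did not pass. Pro-apoptotic genes counted 4 falls and 1 rise of 22, also adjusted over the list alone (median -0.31, which turned to 0.17 with 3 rises and 2 falls with scaling by library size only; camera adjusted p = 0.227, and 0.0101 by fry), and CASP6 fell from 1571 ± 323.6 to 670.4 ± 62.0 CPM. Anti-apoptotic genes counted 6 falls and 1 rise of 17, also adjusted over the list alone (median -0.06, which turned to 0.43 with 5 rises and 2 falls with scaling by library size only; camera adjusted p = 0.484, and 0.111 by fry), with TMBIM6 falling from 188.1 ± 68.5 to 36.5 ± 4.31 CPM. BAX (-0.18) and BMP15 (-0.35) did not pass.

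**Figure D3:**
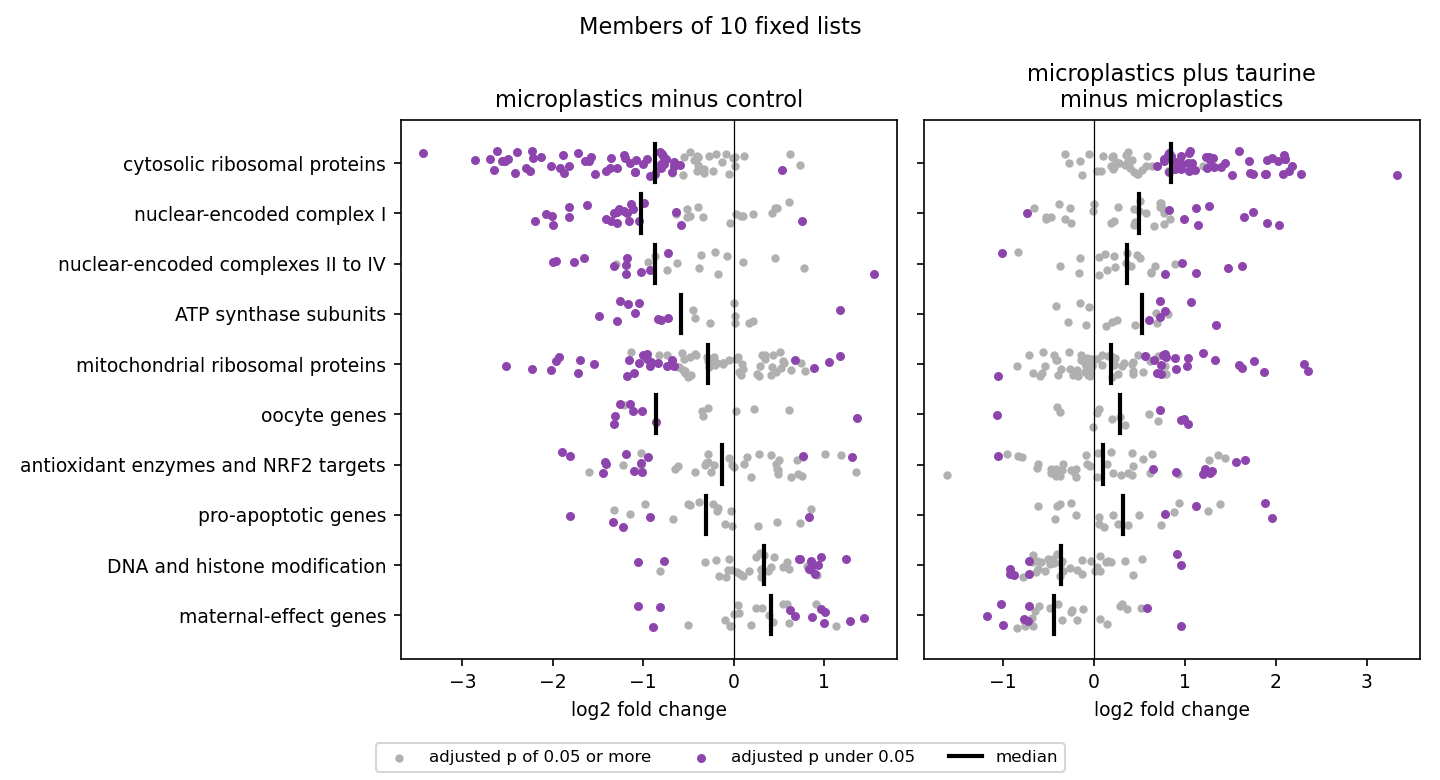
Log2 fold change of each measured member of 10 gene lists in microplastics minus control (left) and microplastics plus taurine minus microplastics (right), 1 point per gene, purple at an adjusted p under 0.05, with a black bar at the list's median. Cytosolic ribosomal proteins have medians of -0.87 and 0.85 (-0.38 and 0.41 with scaling by library size only). With that scaling the medians of mitochondrial ribosomal proteins, antioxidant and pro-apoptotic genes change sign in both comparisons, and those of complexes II to IV and the oocyte gene list in the second.

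Markers of other cells moved little upward. Of 16 tested cumulus and granulosa markers 0 rose with microplastics by edgeR and 5 fell, SERPINE2 (46.1 to 13.2 CPM), GJA1 (33.8 to 12.6 CPM), PTGS2 (21.2 to 8.77 CPM), VCAN and INHA, while the most abundant, STAR, stood at 283 and 309 CPM and did not pass. VCAN lost its call without control 1 (-0.58), control 2 (-0.55), microplastics 1 (-0.50), microplastics 2 (-0.56) or microplastics 3 (-0.62), and INHA, under 1 CPM in both groups, without any 1 of the control or microplastics libraries (adjusted p = 0.056 to 0.138). The erythroid gene HBA fell, HBA1 fell with a call lost without control 1 (-1.21), microplastics 1 (-1.61) or microplastics 3 (-1.56), CNN1 of the stroma list rose with a call lost without control 1 (1.19), and 0 of 5 endothelial markers were called by edgeR. CD3E of the leukocyte list fell, a call lost without control 1 (-0.95), control 2 (-0.67), microplastics 1 (-0.69), microplastics 2 (-0.92), microplastics 3 (-0.88) or taurine 2 (-0.84). Of 20 oocyte markers 3 rose (NLRP5, PABPC1L and ZAR1) and 6 fell (ZP2, ZP3, GDF9, BTG4, H1-8 and OOSP2). NLRP5 lost its call without control 1 (0.85), control 2 (0.89), microplastics 1 (1.00), microplastics 2 (1.02) or microplastics 3 (1.05), ZP2 without microplastics 1 (-0.99) or microplastics 3 (-1.09), and GDF9 as given above.

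The count of 3213 genes (5038 at an unadjusted p under 0.05) was 1715 without control 1, 1892 without control 2, 1876 without microplastics 1, 2059 without microplastics 2 and 1751 without microplastics 3, and 5110 with control 3 and taurine 3 left out. Scaling by library size only moved the median of all genes from 0.04 to 0.52 and called 4004 genes higher and 876 lower, so that 82.0% of calls were higher against 39.8%. Less that median of all genes, medians were -0.31 for mitochondrial ribosomal proteins, -0.18 for antioxidant, -0.34 for pro-apoptotic and -0.09 for anti-apoptotic genes. A change of scaling moves all genes of a library alike, so this subtraction nearly restores the TMM medians by design. It does not show which scaling is right.

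The second comparison asked what taurine changed in oocytes that also had microplastics. THOC6 rose from 5.90 ± 1.34 to 133.7 ± 30.8 CPM (log2 4.50, adjusted p = 8.31e-06), NUDCD2 from 8.35 ± 2.16 to 106.4 ± 8.53 CPM and SMIM11 from 10.1 ± 4.70 to 136.2 ± 31.1 CPM. HSD11B2, which inactivates cortisol, rose from 10.9 ± 6.30 to 103.1 ± 31.0 CPM. GUSB, a lysosomal glucuronidase, fell from 12.1 ± 0.411 to 2.69 ± 0.688 CPM (log2 -2.16, adjusted p = 0.000385) and NEFH from 24.2 ± 1.98 to 5.95 ± 2.06 CPM. In all, 1878 genes were called, 1333 higher and 545 lower.

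DPP3, PLAC1, VEGFD and FAM200B rose by log2 3.23, 3.58, 3.77 and 3.19. GABRA4 rose by 3.68, a call lost without microplastics 2 (3.34), microplastics 3 (3.17) or taurine 3 (3.48). Falls included FMNL3 (22.6 ± 5.82 to 5.70 ± 0.872 CPM), ITGB5 (17.5 ± 3.30 to 5.56 ± 1.79 CPM), FAM163A, MADD, MAP3K12, NCDN and CRAT, and WASHC1 fell by 1.63 on the log2 scale, a call lost without microplastics 1 (-1.56).

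Of the 77 cytosolic ribosomal protein genes 44 rose and 0 fell by edgeR (51 and 0 adjusted over the list alone), with a median of 0.85 (0.41 with 28 rises and 2 falls with scaling by library size only). RPS19 rose from 7.56 ± 2.73 to 76.4 ± 25.7 CPM and RPL27 from 111.7 ± 18.5 to 336.8 ± 34.7 CPM. Camera gave an adjusted p of 8.62e-17, and the adjusted p = 0.699 with an estimated correlation. With the length trend removed the median was 0.52 (camera adjusted p = 7.8e-07), and it was the only list of 29 called.

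Complex I genes counted 9 rises and 1 fall of 38 (13 and 1 adjusted over the list alone; median 0.50, and 0.06 with 5 rises and 5 falls with scaling by library size only; camera adjusted p = 0.00881, a call lost without taurine 2, at 0.42), with NDUFA6 rising from 43.9 ± 4.74 to 179.8 ± 14.9 CPM. Mitochondrial ribosomal protein genes counted 20 rises and 1 fall of 77 (21 and 1 adjusted over the list alone; camera adjusted p = 0.0286), and their median of 0.19 turned to -0.25 with scaling by library size only (11 rises and 7 falls). Their call was lost without taurine 2 (0.09), with a filter of 5 CPM in 3 libraries (0.15) and with fry (adjusted p = 0.0507), and that of complex I with fry (adjusted p = 0.0866). MRPL22 rose from 40.04 ± 4.68 to 199.1 ± 8.27 CPM and MRPL39 from 131.5 ± 6.50 to 445.3 ± 82.1 CPM. The adjusted p = 0.699 with an estimated correlation for both lists. Complexes II to IV (5 rises and 1 fall of 25, also adjusted over the list alone; median 0.37, which turned to -0.07 with 3 rises and 3 falls with scaling by library size only) and ATP synthase (6 rises and 0 falls of 18 by edgeR, 7 and 0 adjusted over the list alone; median 0.53, and 0.09 with 1 rise and 1 fall with scaling by library size only) did not pass camera, at adjusted p of 0.0808 and 0.0551, and SDHD and COX7B rose by log2 1.63 and 1.12. With the length trend removed the medians were 0.12 for complex I, -0.13 for mitochondrial ribosomal proteins, 0.01 for complexes II to IV and 0.11 for ATP synthase. The 3 called lists became 6 without control 1, 5 without control 2, 5 without control 3, 6 without microplastics 2, 7 without taurine 1 and 1 without taurine 2.

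CAT rose from 129.0 ± 14.8 to 312.6 ± 85.1 CPM (log2 1.28, adjusted p = 0.00191) and PRDX3 from 115.3 ± 3.63 to 365.8 ± 47.8 CPM. Antioxidant genes counted 8 rises and 1 fall of 46 (11 and 4 adjusted over the list alone; camera adjusted p = 0.396, and 0.0507 by fry), with a median of 0.10 that turned to -0.33 with scaling by library size only (5 rises and 7 falls). Of the pro-apoptotic genes 4 rose and 0 fell by edgeR of 22, also adjusted over the list alone (median 0.32, which turned to -0.12 with 3 rises and 1 fall with scaling by library size only; camera adjusted p = 0.0895, and 0.00567 by fry), CASP9 among them, from 2.27 ± 0.148 to 8.41 ± 2.67 CPM. GDF9 (0.35), BMP15 (0.28), SOD1 (0.42), SOD2 (-0.35), GPX4 (-0.47) and BAX (0.21) did not pass. GPX1 (1.45) did not pass, and its 3 taurine libraries held 6.27, 9.02 and 58.8 CPM, the last in taurine 3, without which the value was -0.24.

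Of the cumulus and granulosa markers PTGS2 and SERPINE2 rose, VCAN rose with a call lost without microplastics 1 (0.68), and INHA rose with a call lost without microplastics 1 (adjusted p = 0.0515). INHA stood at 0.713, 0.386 and 9.19 CPM in taurine 1, 2 and 3. Taurine 3 also stood apart in the stroma genes LUM (40.4 CPM against 0 and 0) and POSTN (12.3 against 0.238 and 0.0483), and in TNFAIP6 (33.3 against 1.05 and 1.16), which was at 66.1 CPM in control 2. The erythroid gene HBA rose by log2 1.09, a call lost without microplastics 1 (1.00) or microplastics 2 (0.99). Of 20 oocyte markers 4 rose (BTG4, H1-8, OOSP2 and ZP2) and 3 fell (NLRP5, PABPC1L and ZAR1), and BTG4, at log2 1.42 (adjusted p = 0.000611), alone kept its call with each library left out. H1-8 lost it without microplastics 3 (0.83), OOSP2 without microplastics 2 (0.67), microplastics 3 (0.62), taurine 1 (0.57) or taurine 2 (0.77), and ZP2 without microplastics 1 (0.91), microplastics 2 (1.14), microplastics 3 (1.01) or taurine 3 (0.60). NLRP5 lost it without microplastics 1 (-1.01), microplastics 2 (-1.04), microplastics 3 (-1.07) or taurine 3 (-0.78), and ZAR1 without microplastics 1 (-0.69), microplastics 2 (-0.64), taurine 2 (-0.71) or taurine 3 (-0.61). PABPC1L lost it without control 2 (-1.07), microplastics 1 (-1), microplastics 2 (-1.08), microplastics 3 (-1.18), taurine 1 (-0.82) or taurine 3 (-1.01).

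The count of 1878 genes (3832 at an unadjusted p under 0.05) was 888 without microplastics 1, 1009 without microplastics 2, 973 without microplastics 3 and 1211 without taurine 3. Scaling by library size only moved the median of all genes from -0.02 to -0.45 and called 601 genes higher and 2488 lower, so that 19.5% of calls were higher against 71.0%. Less that median of all genes, medians were 0.20 for mitochondrial ribosomal proteins, 0.38 for complexes II to IV, 0.12 for antioxidant and 0.33 for pro-apoptotic genes. As in the first comparison, this subtraction nearly restores the TMM medians by design and does not show which scaling is right.

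The series title speaks of recovery, so genes called between microplastics and control were followed into the taurine libraries. Calmodulin gene CALM2 was at 4513 ± 862.9 CPM in control, 731.1 ± 157.2 with microplastics and 4017 ± 188.1 with taurine. The LIM-domain genes LHX2 and LMO4 ran 181.3 ± 22.7, 28.4 ± 3.25 and 157.4 ± 7.94 CPM, and 463.9 ± 94.2, 61.1 ± 11.7 and 375.8 ± 50.4 CPM. SNX3, PDCD5, MRPL22 and DPP3 were called in both comparisons with opposite signs as well. The median log2 change of the 1935 lower genes was -1.08 between microplastics and control and -0.20 between taurine and control, and that of the 1278 higher genes 1.03 and 0.30. Called without 1 control and read against that control, lower genes had medians of -0.31 (control 1), -0.22 (control 2) and 0.04 (control 3) in taurine, and higher genes 0.37, 0.25 and -0.14, so the sign of what remained turned with control 3.

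**Figure D4:**
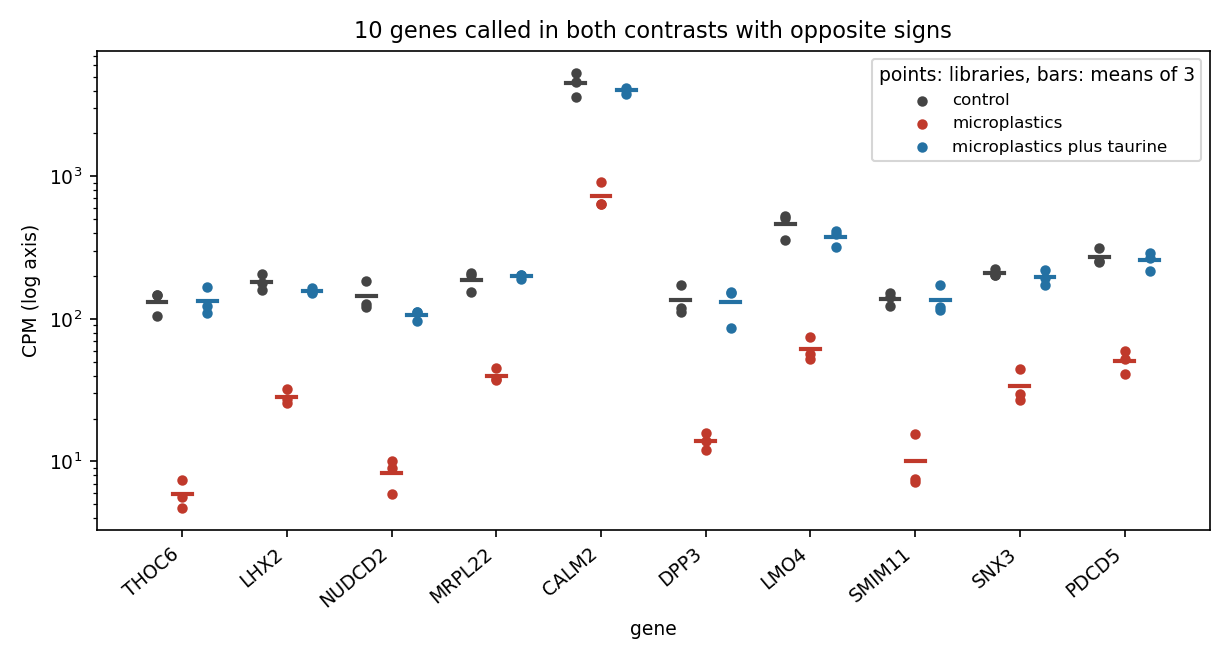
CPM on a log axis of the 10 genes with the smallest adjusted p in both comparisons with opposite signs, 1 point per library and a bar at the mean of 3 libraries. In THOC6 the means are 132.7 in control, 5.90 with microplastics and 133.7 with microplastics and taurine.

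With each microplastics library left out in turn, 98.0% ± 0.4 (SD over 3 choices) of genes called without it were closer to the control side in the taurine libraries than in that library, against 49.9% in simulated data with no return. Genes were drawn independently in that simulation, so it does not show how far the share strays when genes move together. The share shows that the taurine libraries lay nearer to control than the microplastics libraries did. It does not separate an effect of taurine from a difference in handling confined to the microplastics libraries. Nor was it computed with the length trend removed. The 3 choices share the control and taurine libraries, so the SD is not a sampling error. With control 3 and taurine 3 left out the share was 87.1%. Lower with microplastics and higher with taurine were 1208 genes (195 for independent lists), higher and then lower 448 (53), and 0 changed the same way in both by edgeR. The log2 changes of the comparisons correlated across genes, which are not replicates, at -0.844 with a covariance of -0.528, against -0.487 and -0.080 in simulated unchanged groups. The share takes calls and return from different microplastics libraries. The overlaps and the correlation use the same 3 in both comparisons, too few to part into sets of 2, and part of their excess may come from sharing them.

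The third comparison asked how far oocytes with microplastics and taurine differed from control. By edgeR 1 gene was called, an unnamed gene with the ID 539802 that the naming rule takes despite its level. It had 0 reads in every control library, 2.15 ± 0.954 CPM with taurine, at least 13.9-fold higher against a floor of 3 counts per control library, and 5.37 ± 1.04 CPM with microplastics alone (adjusted p = 0.0223). At an unadjusted p under 0.05 there were 753 of the 13206 tested genes. That threshold alone passes nearly as large a share when nothing differs. DESeq2 called 5 genes and limma-voom 1. The call was lost (0 genes) without any 1 control or microplastics library, and 2 genes were called without taurine 3.

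The genes next in order of p did not pass. NOP9 was at 16.01 ± 6.53 CPM with taurine and 4.32 ± 0.223 in control and XPNPEP1 at 25.4 ± 2.58 and 13.3 ± 1.37 CPM (adjusted p = 0.7 and 0.855). DEGS1, a sphingolipid desaturase, was at 258.3 ± 22.3 and 472.5 ± 65.3 CPM, CREG1 at 51.6 ± 15.8 and 116.6 ± 25.1 CPM and ANKRD1 at 3.10 ± 0.0978 and 8.83 ± 2.39 CPM (adjusted p = 0.7, 0.855 and 0.855). NOP9, XPNPEP1, DEGS1 and CREG1 were among the genes called by DESeq2. CAT (-0.13), SOD1 (0.12), SOD2 (0.16), GPX1 (0.80), GPX4 (-0.19), BAX (0.03), GDF9 (-0.98) and BMP15 (-0.06) did not pass, and GDF9 was at -0.16 without control 1.

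Lists of complex I, complexes II to IV and oocyte genes passed camera as lower, with medians of -0.17, -0.27 and -0.18 (adjusted p = 0.0112, 0.0112 and 0.0398), although 0 of their members were called by edgeR or adjusted over the list alone. The adjusted p = 0.994 with an estimated correlation for each, fry called 0 lists, 0 were called with the length trend removed, and 0 without control 1 (-0.04, -0.13 and -0.13) or without taurine 1 (-0.08, -0.20 and -0.04). Complexes II to IV also lost the call without control 2 (-0.23) and oocyte genes without control 3 (-0.20), while the complex I median was -0.33 without control 3, that of complexes II to IV -0.44 without taurine 3 and that of oocyte genes -0.27 without taurine 2. With control 3 and taurine 3 left out, 783 genes were called, 623 higher and 160 lower. The near absence of calls thus depends on these 2 libraries, which were left out after their resemblance to the other group was seen.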

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

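Scaling by library size only, testing transcripts one by one, leaving out control 3 with taurine 3, and removing the length trend were chosen after the results were seen. The cause of each move was not tested, except that a fold limit keeps fewer genes and a left-out library leaves fewer samples.

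The 3213 genes of microplastics minus control became 1820 with an absolute log2 fold change of at least 1, 4880 with library size only (2153 shared) and 5110 with control 3 and taurine 3 left out. The 1878 genes of microplastics plus taurine minus microplastics became 955 with the fold limit and 3089 with library size only. The 1 gene of microplastics plus taurine minus control became 0 with a filter of 5 CPM in 3 libraries, 5 with DESeq2, 4 with transcripts tested one by one, 783 with control 3 and taurine 3 left out and 0 with only the 2 groups compared. Leaving out each library gave 1715 to 4151, 888 to 2146 and 0 to 2 genes.

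Called lists in microplastics minus control, 7 of 29, became 0 with an estimated correlation, 4 with the filter of 5 CPM and 1 with the length trend removed, and ranged from 5 to 7 with a library left out. In microplastics plus taurine minus microplastics, 3 became 0, 6 with only the 2 groups compared and 1 with the length trend removed, and ranged from 1 to 7. In microplastics plus taurine minus control, 3 became 0 with an estimated correlation, 0 with fry and 0 with the length trend removed, and ranged from 0 to 3. The share that moved back, 98.0%, was 87.1% with control 3 and taurine 3 left out and 99.6% in the plain computation, and 94.2% to 98.6% with a library left out.

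With the replicate number as a block, 2417, 1293 and 0 genes, 7, 5 and 3 lists and a share of 98.9% were called or found. There was little sign that the numbers pair the libraries: 2 of 9 same-numbered pairs correlated above 0.1 (range -0.441 to 0.261), and 1 of 9 libraries correlated best with its own number. Same-numbered control and microplastics libraries were at 0.05, 0.176 and 0.261, and pairs with taurine ran from -0.441 to 0.017. The labels state no pairing, and the check does not exclude it.

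Of 234 other values for called lists 181 stayed, 48 lost the call and 5 reversed. Mitochondrial ribosomal medians reversed with library size only (0.208 and -0.247 in the first and second comparison) and with the length trend removed (0.001 and -0.126), and ATP synthase reversed by camera's direction with the length trend removed (-0.107). Of 4724 values for named genes 4311 stayed, 376 lost the call, 13 gained it and 24 reversed, all 24 in genes not called in that comparison. With library size only, microplastics minus control was 0.27 for BAX, 0.18 for SOD1 and 0.13 for BMP15, and microplastics plus taurine minus microplastics was -0.20 for BAX, -0.01 for SOD1, -0.09 for GDF9 and -0.16 for BMP15. With the length trend removed, BAX was 0.33 and -0.18 and SOD1 0.03 in those comparisons. With control 3 and taurine 3 left out, BAX was 0.18 in the first, and GPX1 -0.25 in the second and -1.14 in microplastics plus taurine minus control. With 1 library left out, BAX ranged from -0.33 to 0.18 in the first comparison and -0.12 to 0.43 in the second, and GPX1 from -0.24 (without taurine 3) to 1.90 in the second. In microplastics plus taurine minus control the ranges were -0.30 to 0.38 for BAX (-0.12 without control 1, -0.11 without control 2), -0.89 (without taurine 3) to 1.25 for GPX1, -0.58 to 0.05 for GPX4 (0.05 without control 2 and without taurine 1), -0.26 to 0.12 for BMP15 and -0.37 to 0.02 for CAT. At this depth genes under 0.132 to 0.142 CPM cannot be told from 0 in a library. In simulated counts of microplastics minus control 5 of 50 genes changed 1.5-fold were called. Far fewer genes changed there than the 3213 called in the data, which makes the adjusted threshold stricter. That share is therefore not the detection limit of the real comparison.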

Other observations

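The tests of length on the ribosomal and mitochondrial lists, of maturation, of follicle cell RNA in the control libraries, of exchanged labels and of axis position, the 10 splits of microplastics plus taurine minus control and the symbol families were chosen after the results were seen. With the values known, the maturation test was made stricter, which turned it from argued against to open, and the follicle cell test was narrowed to the microplastics libraries.

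Among 78 families of genes sharing the start of a symbol, ubiquitin-specific proteases (USP) counted 11 rises and 1 fall of 46 with microplastics, with a median log2 change of 0.46 (camera adjusted p = 0.0014), and 0 rises and 6 falls by edgeR with taurine. DHX helicases counted 6 rises and 0 falls of 15 by edgeR (median 0.53, adjusted p = 0.0195) with microplastics. Others passed camera too with microplastics, among them RPL (1 rise and 31 falls of 45) and COX (1 and 10 of 24) as lower and ARHGAP (6 and 0 of 25) as higher. The adjusted p = 0.606 with an estimated correlation for each family named here with microplastics. Families were not tested with the length trend removed, so a part of transcript length in these changes stays open.

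The microplastics libraries differed from control at 3213 genes and from taurine at 1878, and the highest of the other 9 splits of the same 6 libraries called 0 in each case, so that 1 of 10 splits was as large, and 10 splits cannot give a share under 0.05. A bias on transcript length as the whole cause is argued against by the 77.8% of called genes that kept their call and sign once the length trend was removed. More RNA of somatic follicle cells in the microplastics libraries is argued against by 0 of the 6 cumulus and granulosa genes at 5 CPM or more rising by edgeR, while more of it in the control libraries stays open, since 4 of 7 at that level in control fell and STAR, HAS2 and TNFAIP6 did not pass. Less complete maturation stays undecided. Of 4 lists, 3 passed opposite to it by camera with the preset correlation, but 1 once the length trend was removed and 0 with an estimated correlation. These 3 are the cytosolic ribosomal, complex I and complexes II to IV lists described above. Their fall was known when the test was chosen, so they are not separate evidence. Of 20 mRNAs recruited in maturation 3 fell and 17 did not pass (median -0.18). That list was lower, as less complete maturation predicts, at a camera p of 0.0496, of 0.0111 with the length trend removed and of 0.251 with an estimated correlation. Open as hypotheses are also a response to microplastics and a difference in handling that followed the groups, which the labels do not record.

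Lower ribosomal and mitochondrial transcripts with microplastics may in part follow length, since these transcripts are short (median 360 nt for cytosolic ribosomal proteins and 410 nt for complex I). For cytosolic ribosomal proteins the median went from -0.871 to -0.494 and camera still passed, which goes against length as the whole cause, but only at the preset correlation. With an estimated correlation the list did not pass even before removal (camera adjusted p = 0.785). None was estimated after removal, so the test does not settle the question. For the mitochondrial lists the data are consistent with transcript length bias, since all 4 lists had a median under 50% of its former size and lost their calls once the trend was removed. The trend was fitted on all genes with a length, these lists among them. Its removal could therefore also take out part of a change of their own. A loss of short mRNAs in the oocytes and a loss during library preparation would both give a length trend, and nothing here separates them.

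Control 3 and taurine 3 resembled the other group. The split of control 1, control 2 and taurine 3 against control 3, taurine 1 and taurine 2 called 1569 genes where the real split called 1, and 3 of 10 splits called at least as many as the real one. That split is the grouping already seen in the principal components and correlations, so its count restates it and is not independent evidence. Position on the axis that separates microplastics from the other libraries is argued against as the whole cause, since 0 of the 2 libraries correlated best with their own group once it was removed. Exchanged labels of control 3 and taurine 3 are a candidate explanation, since 2 of 2 then still correlated best with the other group (0.139 and 0.126, against -0.273 and -0.299 with their own). This is the same result that argues against axis position, so it is not separate evidence. The gene with ID 539802 kept to the deposited labels, at 0 CPM in control 3 and 1.97 in taurine 3, but it was called by those labels. A batch shared by these libraries would look alike, the labels give none, and the labels were kept as deposited.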
